A study of Mus musculus with 8 samples.

How the data were processed

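Gene expression was measured by RNA sequencing in mouse prospermatogonia, the male germ cells of the fetal testis, at E17.5 (embryonic day). Per the labels, 4 libraries came from Tet1-/- animals (KO 1 to KO 4) and 4 from Tet1+/+ animals (WT 1 to WT 4), all in 1 batch. RNA was taken with TRIzol from snap-frozen cell pellets and treated with DNase I. Libraries of total RNA depleted of ribosomal RNA were made from 5 ng with a SMART-seq Pico Input kit that carries unique molecular identifiers (UMIs). The way the cells were isolated and the kind of Tet1 allele are not given in the sources used here.

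The deposited table holds raw counts per gene and library, as whole numbers with no normalization. The submitters' processing notes name Trim Galore, STAR, featureCounts 1.5.0, edgeR and DESeq2, with no role or order, and the mouse build mm10. Whether reads were collapsed by UMI, the strand setting and the GENCODE release are not given in the sources used here. Overlapping genes on opposite strands and genes with near-identical copies can therefore share or lose reads, and intervals on counts cover counting error only. The table had 55401 genes under versioned Ensembl identifiers. Of these, 55141 matched GENCODE M21 without the version and 54349 with it, and 260 matched no entry. Symbols, biotypes and coordinates were taken from that annotation, on the same assembly as mm10. No library column was left unused, and 6261 genes had a count of 0 in all 8 libraries.

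Total counts ran from 13820764 to 20115250 per library. A count of 0 allowed up to 3 counts, which was between 0.149 and 0.217 CPM (counts scaled to the library size) depending on the library.

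Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the groups, library sizes were scaled by the trimmed mean of M values (TMM), and a quasi-likelihood model with genotype as its only term was fitted without robust dispersion. Differences are KO minus WT on the log2 scale. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Group values are TMM-scaled CPM with their SD (n = 4).

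Before the data were examined, 25 gene lists, the tests, the rule for naming genes and most of the alternatives were fixed. Lists with 5 or more tested members were compared with all other tested genes by camera (limma 3.58.1) with a preset correlation of 0.01, and adjusted over the 25 lists. The same test was run with the correlation estimated from the data. Of the list members, 39 were in 2 or more lists. Marker levels were the mean of log2(CPM + 1) over a list in each library. They were compared by exact two-sided permutation over the 70 splits of the libraries, which can give no p below 0.0286. Separation of the libraries was the mean correlation distance between groups minus that within groups, tested exactly and one-sided over the 35 distinct splits. Genes within 10 Mb of Tet1 were compared with all others by Fisher's exact test.

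The genes named were Tet1, the 10 largest rises and the 10 largest falls, and up to 4 members of each list with the lowest p (up to 2 for marker lists). Rises and falls were taken from passing genes with a mean log2 CPM of 0 or more, no overlap between groups, and a symbol other than a predicted or clone name. A further 46 genes were chosen after their values were seen: members that passed in a list's less common direction where 5 or fewer did so, and cell type genes. Some genes that fall under these choices are not reported singly here; they stay in all counts and list tests.

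The alternatives were DESeq2 1.42.0, limma with library weights, robust dispersion, median-ratio (RLE) and upper-quartile scaling, no low-count filter and a stricter one (CPM of 1 or more in 4 libraries), the replicate number as a block, a somatic marker covariate, a fold threshold, an adjusted p under 0.1, and leaving out each library. List tests were also run with fry, which tests a list against no change, marker levels with a pseudocount of 0.1 and on raw library sizes, separation on the 500 most variable genes, and the Tet1 neighbourhood with windows of 5 and 20 Mb. Scaling on ribosomal protein genes, cyclic loess, thinning to the smallest total, protein-coding genes only, and 10000 abundance-matched random lists were chosen after seeing the data.

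The pipeline was tested on simulated counts with the real library sizes, means and fitted dispersions, with 187 changed genes among 23329 tested. It called 47.9% of changes of 1 and 92.3% of changes of 2 on the log2 scale. None had the wrong sign, and 6 of the 136 calls were unchanged genes. The 1 raised list was called, and 0 of 25 unchanged lists were. A far larger part of the genes passed in the real data (12853 of 24005). The simulation therefore does not give the error rates, signs or list calls to be expected there.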

Results

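RNA sequencing counts were available for 8 libraries of mouse prospermatogonia at E17.5 (embryonic day), 4 labelled KO (Tet1-/-) and 4 labelled WT (Tet1+/+). The total count was 16097892 in KO 1, 19947912 in KO 2, 13820764 in KO 3 and 16356747 in KO 4. It was 18455994 in WT 1, 15589443 in WT 2, 20115250 in WT 3 and 14732396 in WT 4. Totals did not differ detectably between the groups (exact two-sided permutation p = 0.714). TMM factors ran from 0.885 to 0.984 in the libraries labelled KO and from 1.03 to 1.11 in those labelled WT (exact p = 0.0286, adjusted p = 0.229 over 8 library measures). Replicates differed by more than counting noise, with a chi-square per degree of freedom between 7.87 and 27.7 for pairs within a group. The biological coefficient of variation was 0.217.

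At E17.5 male germ cells are held in cell cycle arrest, and DNA methylation that was erased earlier is being laid down again. TET1 oxidises methylated cytosine and also binds chromatin partners without using its enzyme activity. By its title, the series asks how the part of TET1 that does not depend on catalysis shapes the chromatin on which new methylation is placed in male germ cells. The comparison of the 4 libraries labelled KO with the 4 labelled WT asks which transcripts differ without TET1.

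The Tet1 count went against the labels. Tet1 (ENSMUSG00000047146.17, chromosome 10, 62804570 to 62908996, minus strand, GRCm38) had 31.9 ± 1.95 CPM (SD, n = 4) in the libraries labelled WT and 124 ± 33.4 CPM (SD, n = 4) in those labelled KO. The log2 difference was 1.97 (SE 0.178, edgeR with Benjamini-Hochberg adjusted p = 3.03e-06), and all 4 libraries labelled KO were above all 4 labelled WT. A count per gene cannot show which exons were read, so a transcript that lacks a deleted exon is counted like an intact one. Every direction below therefore refers to the labels as deposited.

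The libraries fell into their labelled groups. The correlation distance between groups exceeded that within groups by 0.0562 (exact one-sided permutation p = 0.0286, the smallest that 35 splits can give). The first principal component held 65.9% of the variance and the second 8.88%.

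**Figure D1:**
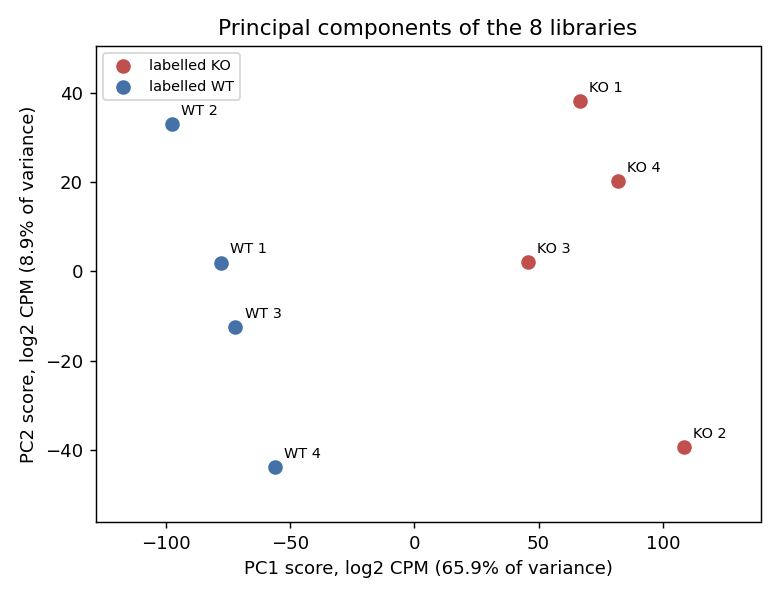
Scores of the 8 libraries on the first and second principal components of log2 CPM of the tested genes, with 1 point per library coloured by its label. All libraries labelled KO lie at 45.9 or above on the first component and all labelled WT at -56.0 or below.

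Of 24005 genes tested, 12853 (53.5%) passed with edgeR at a Benjamini-Hochberg adjusted p under 0.05, 6083 higher and 6770 lower in the libraries labelled KO. Upper-quartile scaling moved the median difference of all genes by -0.24 and gave 4033 higher and 8882 lower, and scaling on ribosomal protein genes moved it by -0.18 and gave 4011 higher and 7728 lower. Cyclic loess moved it by 0.10 and gave 50.7% of its calls as higher, against 47.3% with TMM. With an absolute log2 difference of 1 or more, 2107 genes were higher and 4668 lower. Groups did not overlap for 11612 genes (48.4%), where chance gives 2.86%. Among protein-coding genes, 10080 of 16568 passed, 5136 higher and 4944 lower. The direction depended on abundance. Of 8364 genes with a mean log2 CPM of 4 or more, 5326 passed, 72.2% of them higher. Of 6459 with a mean under 1, 2482 passed, 14.0% of them higher. Counts of list members below are to be read beside these shares. Of the passing genes, 1627 did not pass without KO 4, and 5 of these changed sign.

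The 10 largest rises held genes of the NODAL pathway, which keeps fetal male germ cells in an undifferentiated state. Lefty1 (ENSMUSG00000038793.8, chromosome 1, 180935022 to 180938400) went from 0.855 ± 0.184 CPM (SD, n = 4) in the libraries labelled WT to 69.1 ± 15.2 CPM (SD, n = 4) in those labelled KO, a log2 difference of 6.33. Lefty2, a near-identical neighbour whose reads may not be assigned apart, rose by 6.24 and Nodal by 4.43. The pluripotency factor Sox2 rose by 4.49. Also among them were the histone genes Hist1h2af (4.91), Hist2h2ac (4.80), Hist1h1b (4.74) and Hist1h3g (4.45) and the pseudogene Dppa3-ps (4.54), all of which have close copies elsewhere in the genome. The edgeR adjusted p of the rises named here, by Benjamini-Hochberg, was 5.8e-07 or lower.

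The 10 largest falls were of genes with few counts in the libraries labelled KO. Tgif2-ps1 had 3 counts there in all and 122 in those labelled WT, a depth-scaled ratio of 34.6 (95% counting interval 11.6 to 170.0). Slc10a4 had 4 against 134 counts, a ratio of 28.5 (10.9 to 106.0). Dcc, a netrin receptor gene with 97 against 1557 counts, had a ratio of 13.6 (11.1 to 16.9). The others were Nlrp1c-ps, Trhde, Dach1, Lcn2, Neto1, Chsy3 and Speer4f1, with log2 differences from -4.09 to -3.53. The spread between libraries labelled WT was wide for Dcc, at 21.5 ± 18.4 CPM (SD, n = 4), and for Dach1, at 7.10 ± 7.72 CPM (SD, n = 4). Without WT 2 the ratio of Dcc was 8.35, and those of Dach1 and Neto1 went from 14.0 to 6.83 and from 12.5 to 6.99. Without KO 1 the ratio was 78.4 for Tgif2-ps1 and 43.1 for Slc10a4, and without KO 3 it was 44.5 for Slc10a4 and went from 18.2 to 28.4 for Nlrp1c-ps.

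**Figure D2:**
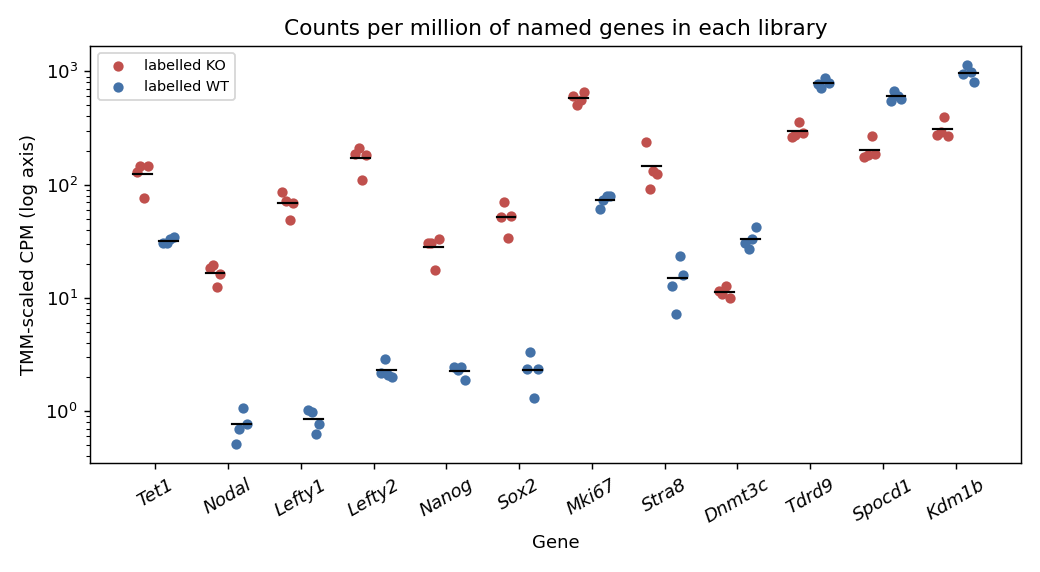
TMM-scaled CPM on a log axis of 12 named genes, picked for display after their values were seen, with 1 point per library and a line at the mean of each label. The libraries labelled KO lie above all those labelled WT for Tet1 through Stra8, and below them for Dnmt3c, Tdrd9, Spocd1 and Kdm1b.

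Of the 25 gene lists, 17 passed against all other genes, 14 higher and 3 lower in the libraries labelled KO. With an estimated correlation only 1 passed, that of mitochondrial, ribosomal RNA and histone transcripts, whose members with the lowest p were histone genes. The number of passing lists does not separate the labelled groups from other groupings, since 2 of the 35 splits of the libraries gave 17. Counts of members below are over all genes tested. Where 5 or fewer members went one way, those named were chosen after their values were seen.

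**Figure D3:**
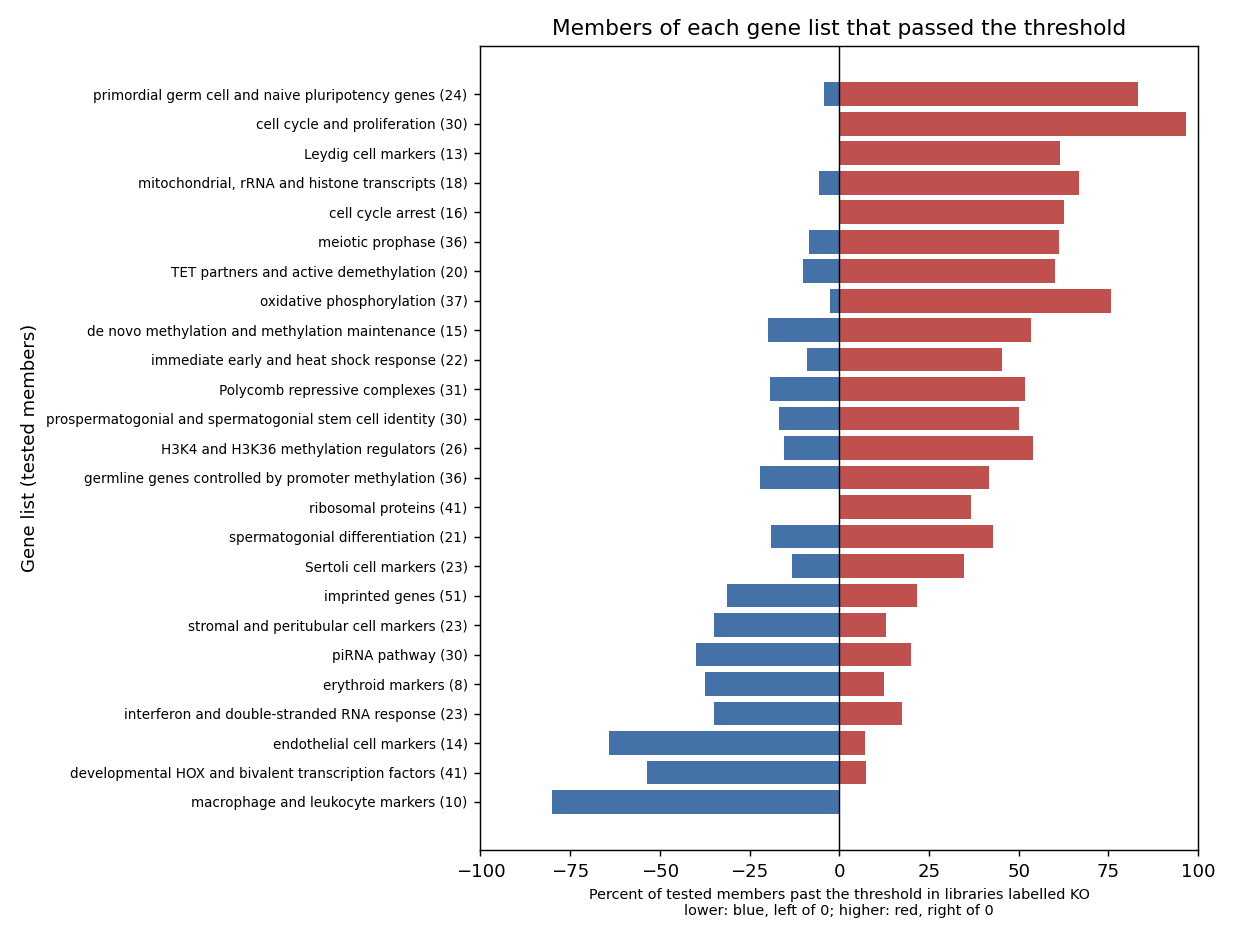
Percent of the tested members of each gene list that passed the threshold, with members higher in the libraries labelled KO to the right of 0 and members lower to the left, ordered by median log2 difference. The cell cycle list has 29 of 30 members higher, and the macrophage list 8 of 10 lower. The median changes sign with upper-quartile and ribosomal protein scaling for spermatogonial differentiation, Sertoli cell markers and ribosomal proteins, and with cyclic loess for ribosomal proteins and erythroid markers.

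The machinery that places and keeps DNA methylation changed in both directions. Of 15 genes, 8 were higher, 3 lower and 4 did not pass, with 11 adjusted over the list alone (camera adjusted p = 0.00593; 0.352 with an estimated correlation; 0.131 against random lists of like abundance). The genes that fell act in de novo methylation: Dnmt3c (log2 difference -1.56), which methylates young retrotransposons in male germ cells, its cofactor Dnmt3l (-1.33) and Dnmt3a (-0.59). Uhrf1 (2.05), which acts in maintenance, Hells (1.70) and Dppa3 (4.04), which has close copies, rose. Of 20 TET partners and demethylation genes, 12 were higher, 2 lower and 6 did not pass, with 14 adjusted over the list alone (camera adjusted p = 0.000589; 0.242 with an estimated correlation). Ogt, whose product binds TET proteins, rose by 1.51 and Hdac1 by 1.07. The 2 that fell were Tet3 (-1.10) and Cxxc4 (-0.67). With upper-quartile scaling 11 of these 20 genes were higher and 5 lower, with ribosomal protein scaling 11 and 4, and with cyclic loess 12 and 5.

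Chromatin regulators changed in both directions. Of 31 Polycomb genes, 16 were higher, 6 lower and 9 did not pass, with 22 adjusted over the list alone (camera adjusted p = 0.0302; 0.352 with an estimated correlation). Mtf2 rose by 0.95 and Rbbp7 by 0.96, and Phc2 fell by 0.76. Of 26 regulators of H3K4 and H3K36 methylation, 14 were higher, 4 lower and 8 did not pass, with 18 adjusted over the list alone (camera adjusted p = 0.0302; 0.387 with an estimated correlation). The H3K36 methyltransferase gene Setd2 rose by 1.30. Kdm1b, which encodes an H3K4 demethylase, fell by 1.66, from 969 ± 139 to 307 ± 60.2 CPM (SD, n = 4), and the others that fell were Kdm1a (-0.51), Kmt2b (-0.51) and Cxxc1 (-0.48). Both lists lost their call with upper-quartile scaling (adjusted p = 0.129 and 0.151), with ribosomal protein scaling (0.0761 and 0.129), with the stricter filter (0.0676 for each) and with coding genes only (0.107 and 0.104). With upper-quartile scaling 11 Polycomb genes were higher and 7 lower, and 10 and 6 of the regulators of H3K4 and H3K36 methylation. Against random lists of like abundance the adjusted p was 0.256 and 0.613.

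The piRNA pathway, which directs methylation to transposons, had 6 members higher, 12 lower and 12 not passing of 30, with 20 adjusted over the list alone. Its list test did not pass (camera adjusted p = 0.0951; 0.606 with an estimated correlation) but did without WT 2 (0.0306), with upper-quartile scaling (0.0280), with ribosomal protein scaling (0.0372), with a somatic marker covariate (0.0281) and against random lists of like abundance (0.00938). With upper-quartile scaling 3 members were higher and 17 lower, with ribosomal protein scaling 3 and 15, and with cyclic loess 4 and 17. Spocd1 fell by 1.57, Tdrd9 by 1.41, Mael by 1.13 and Mov10l1 by 0.82. Of 36 germline genes controlled by promoter methylation, 15 were higher, 8 lower and 13 did not pass, with 25 adjusted over the list alone (camera adjusted p = 0.239; 0.636 with an estimated correlation); without a low-count filter the list passed (0.00814), and with upper-quartile scaling, ribosomal protein scaling and cyclic loess 13 were higher and 11 lower. Of 51 imprinted genes, 11 were higher, 16 lower and 24 did not pass, with 27 adjusted over the list alone (camera adjusted p = 0.265; 0.606 with an estimated correlation). The balance depended on the scaling, with 9 higher and 25 lower with upper-quartile scaling, 9 and 19 with ribosomal protein scaling and 11 and 20 with cyclic loess. Mirg (-2.07) and Rtl1 (-1.87), which lie on opposite strands of 1 imprinted cluster, and Zrsr1 (-1.21) fell, and Peg3 rose by 1.26.

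Pluripotency and meiotic genes were mostly higher in the libraries labelled KO, and genes of the other germ cell states changed in both directions. Of 24 primordial germ cell and pluripotency genes, 20 were higher, 1 lower (Klf4, -0.47) and 3 did not pass, with 22 adjusted over the list alone (camera adjusted p = 4.12e-13; 0.242 with an estimated correlation). Nanog rose by 3.61, Prdm14 by 3.15 and Dppa5a, which has close copies, by 4.15. Of 30 prospermatogonial and spermatogonial stem cell genes, 15 were higher, 5 lower and 10 did not pass, with 24 adjusted over the list alone (camera adjusted p = 6.33e-06; 0.242 with an estimated correlation; 0.154 against random lists of like abundance). Beside Lefty1, Lefty2 and Nodal, Dmrt1 rose by 1.45, and those that fell were Tspan8 (-1.92), T (-1.31), Eomes (-0.70), Mcam (-0.64) and Taf4b (-0.37). Of 36 meiotic prophase genes, 22 were higher, 3 lower and 11 did not pass, with 25 adjusted over the list alone (camera adjusted p = 4.86e-05; 0.381 with an estimated correlation). Stra8, which marks entry into meiosis, rose by 3.30 and the cohesin gene Smc1b by 1.95, and Brdt (-1.16), Spo11 (-0.96) and Rec114 (-0.52) fell. Of 21 spermatogonial differentiation genes, 9 were higher, 4 lower and 8 did not pass, with 15 adjusted over the list alone (camera adjusted p = 0.0152; 0.292 with an estimated correlation). Its median of 0.12 was -0.12 with upper-quartile and -0.08 with ribosomal protein scaling, and against random lists of like abundance its direction reversed (adjusted p = 0.868). The list lost its call with coding genes only. Sohlh2 rose by 2.87 and Neurog3 by 2.94, and Rarb (-0.94), Rhox13 (-0.90), Sohlh1 (-0.57) and Crabp1 (-0.40) fell. Calls near the threshold were lost in several settings. Klf4 lost its call without KO 1 (edgeR adjusted p = 0.0565) and Taf4b without KO 1, KO 4 or WT 3 (0.0556 to 0.0785). Eomes lost it without KO 1, KO 3, KO 4, WT 2 or WT 3 (0.0706 to 0.157) and Rec114 without KO 2, KO 3, WT 1 or WT 3 (0.0703 to 0.102). Crabp1 lost it without KO 2, KO 4 or any library labelled WT (0.0747 to 0.186). With DESeq2 the call was lost for Taf4b (0.0533), Rec114 (0.0538), Eomes (0.0722) and Crabp1 (0.0989), and without a low-count filter for the same 4 (0.0551 to 0.135). In the replicate block it was lost for Rec114 (0.0612) and Crabp1 (0.0872), and with RLE scaling for Crabp1 (0.0615). With a somatic marker covariate it was lost for Rec114, Crabp1 and Eomes (0.0548 to 0.117), with thinning for Crabp1 and Eomes (0.0501 and 0.0598), and with cyclic loess for Eomes (0.193).

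Proliferation genes were higher in the libraries labelled KO. Of 30 cell cycle genes, 29 were higher, 0 lower and 1 did not pass, with 29 adjusted over the list alone (camera adjusted p = 2.92e-26; 0.0747 with an estimated correlation). Their median log2 difference was 1.27. Mki67, a marker of cycling cells, went from 72.6 ± 8.64 to 581 ± 64.8 CPM (SD, n = 4), a log2 difference of 3.00. Of 16 arrest genes, 10 were also higher, 0 lower and 6 did not pass, with 11 adjusted over the list alone (camera adjusted p = 0.000389; 0.197 with an estimated correlation), and Cdkn1a rose by 2.96 and Trp53 by 2.33. With upper-quartile scaling 8 arrest genes were higher and 3 lower, with ribosomal protein scaling 8 and 2, and with cyclic loess 10 and 2. Of 22 immediate early and heat shock genes, 10 were higher, 2 lower and 10 did not pass, with 12 adjusted over the list alone (camera adjusted p = 0.0134; 0.381 with an estimated correlation; 0.127 against random lists of like abundance). Ier2 rose by 3.45 and Jun by 1.99, and Fosl2 (-0.88) and Egr2 (-0.77) fell.

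Developmental transcription factors leaned lower. Of 41 HOX and bivalent genes, 3 were higher (Msx1, 1.45, and Otx2, 1.31, among them), 22 lower and 16 did not pass, with 25 adjusted over the list alone (camera adjusted p = 0.0134; 0.590 with an estimated correlation). Pax2 fell by 1.87 and Hoxb4 by 1.53. Otx2 lost its call without KO 1 (edgeR adjusted p = 0.0603) or KO 2 (0.0515), and with upper-quartile (0.0539) and ribosomal protein scaling (0.0520). With cyclic loess 7 were higher and 16 lower, with a median of -0.61. Random lists of like abundance also leaned lower (median -0.43 against -0.94), and against them the adjusted p was 0.0760. Of 23 interferon genes, 4 were higher (Isg15, 2.26; Oasl2, 1.85; Ddx58, 1.33; Zbp1, 1.03), 8 lower and 11 did not pass, with 12 adjusted over the list alone (camera adjusted p = 0.496; 0.606 with an estimated correlation).

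Housekeeping lists were examined, and a mixed list that also holds replication-dependent histone transcripts and so is no plain control. Of 18 mitochondrial, ribosomal RNA and histone transcripts, 12 were higher, 1 lower (Neat1, -1.24) and 5 did not pass, with 14 adjusted over the list alone (camera adjusted p = 1.77e-13; 0.0137 with an estimated correlation). Hist1h1c rose by 3.57 and H2afx by 2.36. These, Hist1h1b and Hist1h3a had the lowest p of the list, and all are histone genes. Mitochondrial ribosomal RNA was 8.48% of counts in the libraries labelled WT and 8.92% in those labelled KO (exact two-sided permutation p = 0.514). Of 37 oxidative phosphorylation genes, 28 were higher, 1 lower (Uqcrc1, -0.41) and 8 did not pass, with 29 adjusted over the list alone (camera adjusted p = 9.54e-08; 0.242 with an estimated correlation), and Ndufa4 rose by 1.76 and Cyc1 by 1.39. Of 41 ribosomal protein genes, 15 were higher, 0 lower and 26 did not pass, with 15 adjusted over the list alone (camera adjusted p = 0.00582; 0.606 with an estimated correlation). Rpl10 rose by 2.01 and Rps23 by 1.55. The median of this list, 0.13, was -0.11 with upper-quartile scaling, -0.07 with ribosomal protein scaling and -0.10 with cyclic loess, and against random lists of like abundance it leaned lower (adjusted p = 0.613), so its direction was not settled.

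Markers of other testis cells were present and did not move together. Of 14 endothelial markers, 1 was higher (Fli1, 1.32), 9 lower and 4 did not pass, with 10 adjusted over the list alone (camera adjusted p = 0.0229; 0.352 with an estimated correlation; 0.127 against random lists of like abundance). Of 10 macrophage markers, 0 were higher, 8 lower and 2 did not pass, with 8 adjusted over the list alone (camera adjusted p = 0.0471; 0.292 with an estimated correlation; 0.127 against random lists of like abundance). The macrophage call was also lost without KO 2 (0.0654), KO 4 (0.0613), WT 1 (0.0531) or WT 4 (0.0731), with upper-quartile (0.0845) and ribosomal protein scaling (0.0653), without a low-count filter (0.0592), with the stricter one (0.0676), in the replicate block (0.0523), with thinning (0.0842) and with coding genes only (0.0729). With cyclic loess 6 endothelial and 4 macrophage markers were lower. Of 23 stromal markers, 3 were higher (Tcf21, 1.27, and Col1a1, 0.65, among them), 8 lower and 12 did not pass, with 11 adjusted over the list alone (camera adjusted p = 0.172; 0.606 with an estimated correlation). Of 23 Sertoli markers, 8 were higher, 3 lower (Tesc, -1.98, Sox10, -1.27, and Dhh, -0.83) and 12 did not pass, with 11 adjusted over the list alone (camera adjusted p = 0.496, and 0.767 with an estimated correlation). The median of 0.02 was -0.22 with upper-quartile and -0.16 with ribosomal protein scaling. Without KO 4, 6 Sertoli markers were higher. Inha (0.71, edgeR adjusted p = 0.0660) and Nr5a1 (-0.27, 0.461) lost their call there. Dmrt1, with the lowest p of the Sertoli list, is on the prospermatogonial list too. Of 8 erythroid markers, 1 was higher (Hba-a1, 1.34, with a near-identical copy), 3 lower (Slc4a1, -1.90, and Alas2, from 18.5 to 9.25 CPM, among them) and 4 did not pass, with 4 adjusted over the list alone (camera adjusted p = 0.505; 0.606 with an estimated correlation); the median of -0.35 was 0.15 with cyclic loess. Dhh lost its call without any library except KO 1 or WT 1 (edgeR adjusted p = 0.0627 to 0.0878), and with DESeq2, without a low-count filter, in the replicate block, with library weights, with a somatic marker covariate and with cyclic loess (0.0742 to 0.454). Hba-a1 lost it without KO 4, WT 1, WT 2 or WT 3 (0.0622 to 0.0949), and with upper-quartile (0.0588) and ribosomal protein scaling (0.0531).

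Leydig cell markers rested on 1 library. Of 13 tested, 8 were higher, 0 lower and 5 did not pass, with 8 adjusted over the list alone (camera adjusted p = 0.0951; 0.606 with an estimated correlation). Without KO 4, 3 were higher: Ptch1, Fads2 and Scarb1. The list passed without KO 1 (0.0371), KO 2 (0.0273) or KO 3 (0.0351), with upper-quartile (0.0337) and ribosomal protein scaling (0.0288), without a low-count filter (0.00758), with a somatic marker covariate (0.00192) and against random lists of like abundance (0.001). With cyclic loess 2 members were higher. Cyp17a1, which encodes an enzyme of androgen synthesis, had 862 CPM in KO 4 and between 1.55 and 4.70 CPM in KO 1 to KO 3, and its log2 difference went from 6.61 to 0.45 without KO 4. Cyp11a1 went from 4.50 to -0.77, Hsd3b1 from 4.64 to -0.75, Star from 3.19 to -0.14 and Nr5a1 from 2.15 to -0.27. Nr5a1 also lost its call without any 1 library labelled WT (edgeR adjusted p = 0.0592 to 0.0999), and Cyp11a1 without WT 1 (0.0532). All these genes from Cyp17a1 to Nr5a1 lost it in the replicate block (edgeR, 0.143 to 0.657) and with robust dispersion (0.0810 to 0.182). They also lost it in limma with library weights (0.178 to 0.291) and with cyclic loess (0.229 to 0.534). Nr5a1 lost it with upper-quartile (0.0755) and ribosomal protein scaling (0.0517), and Scarb1 with cyclic loess (0.104).

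Marker levels were compared by exact two-sided permutation over 7 lists. All 4 libraries labelled KO were below all 4 labelled WT for stromal (2.999 ± 0.141 against 3.27 ± 0.262, SD, n = 4), endothelial (2.17 ± 0.109 against 2.70 ± 0.188) and macrophage markers (0.909 ± 0.126 against 1.28 ± 0.0434), and above them for prospermatogonial genes (5.24 ± 0.198 against 4.33 ± 0.0569). Each had an exact p of 0.0286, the smallest possible, and an adjusted p of 0.05, which did not pass. The prospermatogonial list holds Lefty1, Lefty2 and Nodal, which rose by 6.33, 6.24 and 4.43. Its median log2 difference was 0.39 and 5 of its 30 members fell, so the level does not stand for the whole list. The exact p was 0.0571 for erythroid, 0.343 for Leydig and 0.6 for Sertoli markers. The stromal difference of -0.27 was -0.14 without WT 2, and its exact p rose to between 0.0571 and 0.2 without KO 1, KO 2, KO 3, KO 4 or WT 2. The endothelial exact p was 0.0571 without KO 4, the erythroid one 0.0286 without KO 4, and the Sertoli difference of 0.11 was -0.05 and the Leydig difference of 0.78 was 0.04 without KO 4. Germ cell transcripts were abundant in both groups, with Ddx4 at 366 ± 50.2 CPM (SD, n = 4) in the libraries labelled WT and 455 ± 66.7 CPM in those labelled KO (log2 difference 0.31, edgeR adjusted p = 0.0570). Ddx4 passed without KO 3 (0.0200) or WT 3 (0.0271), with DESeq2 (0.0333), with RLE scaling (0.0490) and without a low-count filter (0.0429). Dazl rose by 0.71 (edgeR adjusted p = 0.000360), from 264 ± 45.7 to 431 ± 24.0 CPM (SD, n = 4), with all 4 libraries labelled KO above all 4 labelled WT.

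**Figure D4:**
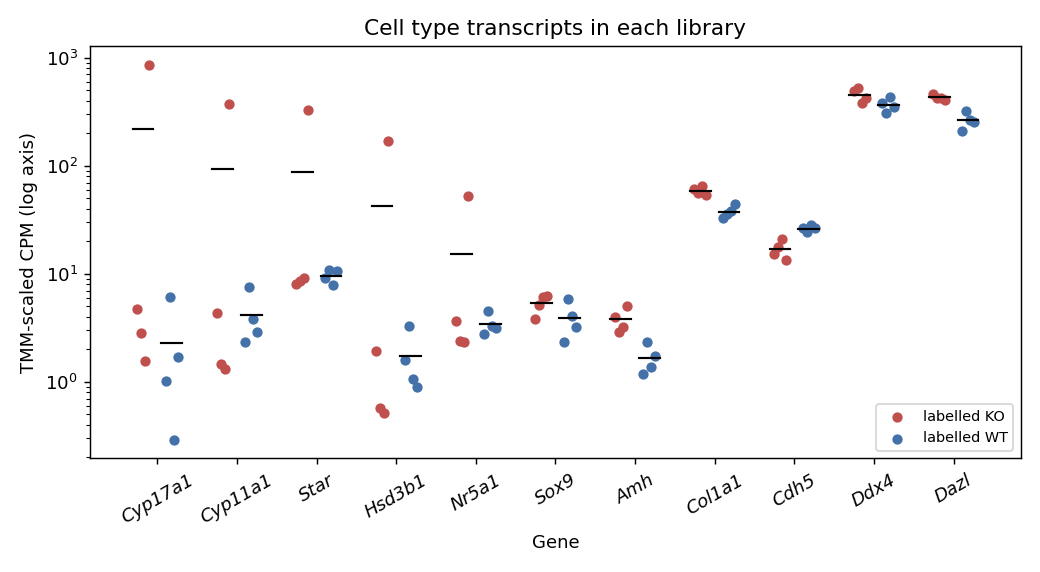
TMM-scaled CPM on a log axis of 11 cell type transcripts, picked for display after their values were seen, with 1 point per library and a line at the mean of each label. The steroidogenic genes at the left are high in KO 4 alone, where Cyp17a1 reached 862 CPM, while the germ cell genes Ddx4 and Dazl are abundant in all 8 libraries.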

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

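The tests on the steroidogenic transcripts in KO 4 were chosen after the result was seen. The items here are single libraries that lay far from the other 3 of their label, by Dixon's ratio, among 312 groups of 4 tested. There were 30 such items, and chance gives about 1 in 20 groups, or 15.6. The groups include 46 genes named after their values were seen, which had 13 of the items, 8 of them in KO 4, so chance is no measure for these. The other 220 groups had 17, where chance gives 11, and 2 of these were in KO 4. KO 4 had 10 of them, WT 2 had 7, KO 2, KO 3 and WT 3 had 3 each, WT 4 had 2, and KO 1 and WT 1 had 1 each.

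In KO 4, the level of Leydig cell markers was 5.50, against 2.42 to 2.74 in the other libraries labelled KO. Cyp17a1 was at 862 CPM, Cyp11a1 at 369 CPM, Star at 326 CPM, Fads2 at 195 CPM, Hsd3b1 at 168.0 CPM, Scarb1 at 111 CPM, Inha at 58.3 CPM and Nr5a1 at 52.4 CPM. Hba-a1 was at 2.06 CPM. These KO 4 values lay above those of KO 1 to KO 3. Insl3, too low to be tested, had 387 counts in KO 4 and at most 2 in any other library.

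A candidate explanation for the steroidogenic transcripts is Leydig cells, or RNA from them, in KO 4. Of the 15 Leydig markers fixed beforehand, 12 had their highest CPM of all 8 libraries in KO 4. Nr5a1 is on the Sertoli list too, and the other 14 are on no other list. The 12 include Cyp17a1, Cyp11a1, Star, Fads2, Hsd3b1, Scarb1, Nr5a1 and Insl3, whose high values in KO 4 are the result to be explained. The count is therefore largely that result again and no separate support. More somatic cells of every kind in KO 4 were not settled. KO 4 had the highest level of all 8 libraries in 1 of the 5 other somatic lists. For stromal, endothelial and macrophage markers all libraries labelled KO lay below all labelled WT, so KO 4 could not be highest there. Among the libraries labelled KO, KO 4 was highest for Sertoli (2.61) and erythroid markers (1.18) and lowest for endothelial markers (2.01). It lay between the others for stromal (3.07) and macrophage markers (0.942). How the cells were isolated is not given in the sources used here. With 1 library no effect of genotype on the steroidogenic transcripts was tested.

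In WT 2, the level of Leydig cell markers was 2.81 and that of stromal markers 3.67, each above the other libraries labelled WT. Also above them were Col3a1 at 56.3 CPM, Fosl2 at 29.6 CPM, Neto1 at 5.40 CPM and Lefty2 at 2.90 CPM, while Hist1h3g was below them at 0.581 CPM.

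In the other libraries, the values above the rest of their label were Spocd1 in KO 3 (267 CPM), Dmrt1 in WT 3 (43.03 CPM), Aurkb in KO 2 (26.4 CPM), Ndufa1 in KO 1 (13.2 CPM), H2afx in WT 4 (26.7 CPM), Hist1h3a in WT 3 (3.31 CPM), Kdm1a in KO 2 (362 CPM) and Sohlh1 in WT 4 (91.0 CPM). The values below the rest were Nanog in KO 3 (17.6 CPM), Rrm2 in KO 3 (28.9 CPM), Ier2 in WT 1 (1.18 CPM), Mx1 in WT 3 (6.43 CPM) and Msx1 in KO 2 (1.02 CPM). None of these was weighed further.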

How the results depend on the processing

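Ribosomal protein scaling, cyclic loess, thinning, coding genes only and abundance-matched lists were chosen after seeing the data, and the other alternatives before. Tet1 stayed higher in the libraries labelled KO and past the threshold in all 21 alternatives (1.67 to 2.17), and the libraries stayed separated in all 10. The count of passing genes ran from 11313 to 13819 in the refits over all biotypes at an adjusted p under 0.05. With coding genes only it was 10181 of 16568 tested, against 10080 coding genes in the main fit. An adjusted p under 0.1, a looser criterion by construction, gave 14557. An absolute log2 difference of 1 or more, a stricter one, gave 6775 (2107 higher). Leaving out 1 library gave 11313 to 13265. Genes higher numbered 4033 with upper-quartile and 4011 with ribosomal protein scaling, which move all genes down. In the replicate block, 11518 genes passed; only 1 of 4 same-numbered pairs correlated above 0.1, KO 1 and WT 1 at 0.148, so the numbers were not taken as pairs. The library names of that pair share a number, and whether these 2 share an origin was not tested; KO 2 and WT 4 correlated higher, at 0.244. The 94 other genes named by the fixed rule kept direction and side in every alternative in which they were tested, which follows from choosing them by p or size. Of 958 values for genes named after they were seen, 92 fell short, 10 gained a call and 4 reversed: without KO 4, Cyp11a1 (-0.77), Hsd3b1 (-0.75), Nr5a1 (-0.27) and Star (-0.14), against highs of 4.95, 5.15, 2.55 and 3.61.

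With an estimated correlation 1 list passed. The adjusted p was then 0.0747 for cell cycle, 0.197 for arrest, 0.242 for TET partners, prospermatogonial, pluripotency and oxidative phosphorylation genes, 0.292 for spermatogonial differentiation and macrophage, 0.352 for methylation, Polycomb and endothelial, 0.381 for meiotic and immediate early, 0.387 for H3K4 and H3K36, 0.590 for HOX and 0.606 for ribosomal protein genes. Against abundance-matched lists it was 0.0760 for HOX, 0.127 for immediate early, endothelial and macrophage, 0.131 for methylation, 0.154 for prospermatogonial, 0.256 for Polycomb and 0.613 for H3K4 and H3K36 genes, and the direction reversed for spermatogonial differentiation (0.868), ribosomal protein (0.613) and erythroid (0.911) genes. Polycomb and H3K4 and H3K36 genes gave 0.129 and 0.151 with upper-quartile scaling, 0.0761 and 0.129 with ribosomal protein scaling, 0.0676 and 0.0676 with the stricter filter, and 0.107 and 0.104 with coding genes only, where spermatogonial differentiation gave 0.0539. Macrophage markers gave 0.0845 with upper-quartile and 0.0653 with ribosomal protein scaling, 0.0592 without a filter, 0.0676 with the stricter one, 0.0523 in the replicate block, 0.0842 thinned, 0.0729 with coding genes only, and 0.0400 to 0.0731 leaving out 1 library. For each of these lists the cause was not tested. Lists that did not pass gained a call 17 times. Of these, 3 came from fry, which tests a list against no change and not against other genes (piRNA, imprinted and interferon), and the others were of the piRNA, Leydig and germline lists. Depth limits the largest falls, which rest on 3 to 97 counts in the libraries labelled KO.

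By exact p before adjustment, the stromal level lost its call with a pseudocount of 0.1 (-0.30); leaving out 1 library gave -0.32 to -0.14 for stromal, -0.61 to -0.46 for endothelial and -0.21 to -0.10 for erythroid markers. On raw library sizes erythroid markers gained a call (-0.23) and the Sertoli difference reversed (-0.00985), as it did without KO 4 (-0.0508, up to 0.202 without KO 2). The odds ratio of genes near Tet1 was 1.08 with a 20 Mb window and 0.980 with 10 Mb, and both 95% intervals include 1; the cause was not tested for these.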

Other observations

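All tests here except the counts over other splits, the comparison of loci with little transcript evidence with coding genes and the test of genes near Tet1 were chosen after the results were seen. Every direction is by the labels as deposited. The bootstrap intervals draw genes as if independent, with the libraries held fixed. They do not cover differences between libraries, so what they argue against is limited to these libraries.

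The 12853 passing genes were not matched by any other split of the libraries: 1 of 35 splits, the labelled one, gave as many, and the highest other gave 0. That share, 0.0286, is the smallest that 35 splits can give. It argues against chance for that count but cannot exclude it, and every other split mixes the labels. The 17 passing lists were matched, since 2 of 35 splits gave 17, so chance cannot be excluded for that number. The other split set KO 1, KO 2, KO 3 and WT 3 against the rest, so it carries part of any difference between the labelled groups. The 16 splits that kept 3 libraries of a label together gave 9 to 17 lists, and the 18 even splits gave 1 to 13. Correlations estimated within the lists reached 0.639, against the preset 0.01.

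Genes with few counts were mostly lower in the libraries labelled KO, with a median log2 difference of -0.99 among coding genes with a mean log2 CPM under 1 (100 higher, 993 lower of 2300). After thinning all libraries to the smallest total the median was -0.988 (95% bootstrap interval -1.03 to -0.936). Thinning keeps the expected ratios of scaled counts, so this value cannot decide on depth. Total counts did not differ detectably between the groups (exact two-sided permutation p = 0.714). Genes detected ran from 33425 to 40194 in the libraries labelled KO and from 38395 to 41470 in those labelled WT (exact two-sided permutation p = 0.114). Gene length was argued against as the whole cause, since the shortest of these genes by exon length (767) had a median of -0.796 (-0.870 to -0.676) and the shortest by span (767) one of -0.648 (-0.750 to -0.553), though the median went from -0.74 at spans up to 10 kb to -1.37 over 100 kb, so span may add to it. With TMM scaling, genomic DNA in the libraries labelled WT was argued against as the whole cause, since it would add as much per kb to every kind of locus. The excess relative to coding genes was 0.0542 (-0.508 to 0.389) at sense intronic loci, 0.692 (0.561 to 0.880) at antisense loci and 1.62 (1.47 to 1.85) at lincRNA genes. It was 0.00386 (-0.368 to 0.218) at processed pseudogenes, which may lose reads to their copies. These ratios were not computed with other scalings. Upper-quartile and ribosomal protein scaling move the median difference of all genes by -0.24 and -0.18, which may change the ratios. As a part of the cause, genomic DNA cannot be told apart from a change in transcripts. The ratio at loci with little transcript evidence was 0.506 (0.416 to 0.706) and spans the bound of 0.5 set beforehand. Loss of TET1 stays open and was not tested.

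Tet1, proliferation and pluripotency genes were higher in the libraries labelled KO. By the Tet1 count, an exchange of the group labels cannot be told apart from a Tet1 allele that keeps a transcript. Tet1 differed by 1.97 in a count that does not show which exons were read. The cell cycle list argues against an exchange, which would make the libraries labelled KO the intact ones. Male germ cells are held in arrest at E17.5, but 29 of 30 cell cycle genes were higher in those libraries. Of 16 arrest genes, 10 were higher there too, so an exchange was not excluded. More somatic cells of every kind, gained by as much as the cell cycle list rose, were argued against. The median of 91 somatic marker genes without KO 4 was -0.312 (95% bootstrap interval -0.700 to -0.0832). A smaller gain was not excluded, because the fall of low-abundance genes may lower such medians. With all libraries, random lists of like abundance had medians of -0.255 for Sertoli, -0.452 for macrophage and -0.398 for erythroid markers. Those for endothelial, stromal and Leydig markers were -0.107, 0.0172 and 0.128. The cell cycle list rose by 1.31 without KO 4 (1.02 to 1.66). A gain of 1 cell type by as much was argued against for Sertoli (0.00177, -0.511 to 0.407), Leydig (0.168, -0.698 to 0.453), stromal (-0.167, -0.796 to -0.00810), endothelial (-0.721, -1.20 to -0.284) and macrophage markers (-1.12, -1.45 to -0.535). Erythroid cells cannot be told apart with 8 markers (-0.229, -1.23 to 1.05). Cycling cells of a type already present could raise cell cycle genes more than its markers, so these values do not exclude them. A larger share of germ cells was argued against as the whole cause, since the median of the piRNA list, which holds mostly germ-cell-specific genes, was -0.141 (-0.522 to 0.273), below that of the cell cycle list, 1.27 (0.980 to 1.60), though Dazl rose by 0.71. The intervals in this paragraph leave out differences between libraries and treat the genes of a list as independent. Correlations estimated within these lists ran from 0.0294 (erythroid) to 0.637 (Leydig), so the intervals are too narrow where these are high. What they argue against is therefore limited to these libraries. Loss of TET1 and a difference in developmental stage between the groups stay open, and neither was tested.

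Of 164 genes within 10 Mb of Tet1, 87 passed (53.0%), against 53.5% of all others, with an odds ratio of 0.980 (95% interval 0.712 to 1.35, Fisher's exact two-sided p = 0.937).

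Gene families were looked at after the data were seen, with camera over 7 families in edgeR and Benjamini-Hochberg adjustment. Of 56 replication-dependent histone genes, 48 were higher and 0 lower (adjusted p with an estimated correlation 0.0105), and the count of 48 was the same with upper-quartile, ribosomal protein and RLE scaling and with cyclic loess. Reads shared between these near-identical genes were not examined. Of 81 olfactory receptor genes, 1 was higher and 48 lower (0.185), and with cyclic loess 2 were higher and 26 lower. Of 36 keratin genes, 0 were higher and 29 lower (0.156), and with cyclic loess 1 was higher and 26 lower. Of 45 collagen genes, 2 were higher and 27 lower (0.156). Of 387 zinc finger genes named Zfp, 166 were higher and 40 lower (0.0894), but 107 and 73 with upper-quartile and 105 and 56 with ribosomal protein scaling. Of 18 mitochondrially encoded tRNA genes, 13 were higher and 0 lower (0.444), and 10 were higher with upper-quartile and ribosomal protein scaling. Of 614 X-linked coding genes, 249 were higher and 111 lower (0.0931), but 169 and 151 with upper-quartile and 168 and 128 with ribosomal protein scaling, so their lean depends on the scaling. No family changed the sign of its median under those settings, and 1 of the 7 passed with an estimated correlation.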
